A study of Rattus norvegicus with 2 samples.

How the data were processed

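Myocardium of spontaneously hypertensive rats was sampled after 12 weeks of KXH (Jiangya Kangxian formula, high dose, 9.6 g/kg) or distilled water. Per the labels' protocols, frozen tissue was extracted with Trizol and sequencing libraries were made from total RNA with an Illumina TruSeq RNA kit. There were 2 libraries, 1 per group, each with a protein-coding and a lncRNA table, 4 tables in all. Groups were taken from the agent named in the labels.

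The deposited tables list for each gene or transcript a whole count of reads, which the column heading describes as unique. The count columns add up to the total in each heading. The deposited RPKM values equal the count per kilobase of the listed length per 1000000 reads of that table's own total, checked on each listed value to within a relative difference of 1e-09. The lncRNA and protein-coding tables have separate totals, so RPKM values of the 2 kinds of RNA are not on a common scale. Only genes or transcripts with at least 1 read are listed, and one absent from a table was taken as 0 reads. The deposited percent coverage was used only to describe depth. Among rows with at least 200 reads its median was 98.9% in both protein-coding tables. Per the submitters' processing notes, Bowtie 0.12.2 and the rn6 assembly were used, with no role given. The annotation, the counting program, the use of strand and any filters are not given in the sources used here. Without strand, reads of overlapping antisense transcripts cannot be told apart, and reads of near-identical genes can be split or lost when only unique reads are kept. Coordinates of lncRNAs are those of the tables, which name no assembly.

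From the RPKM values, the log2 ratio of KXH over water was computed with 1 added to each value for protein-coding genes and 0.1 for lncRNAs, which shrinks the ratios of genes with low values. Genes with a mean of at least 1 RPKM and lncRNAs with a mean of at least 0.5 RPKM were kept. With 1 library per group no test, p-value or standard error between the treatments is possible, and counts of genes at least 2-fold apart describe these libraries. Ratios printed as fold are RPKM ratios without anything added. Their 95% intervals are exact Clopper-Pearson intervals on the share of a gene's reads that came from the KXH library, given both totals. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Where a library had 0 reads, the fold is a bound against a floor of 3 reads in that library. The number of 2-fold differences that counting error alone would give was simulated 50 times.

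Before the data were examined, 46 gene lists for pathways, complexes and cell types were fixed, with a further list of 28 single genes. A list with at least 5 measured members was described by its median log2 ratio and its percentile among 10000 random lists of the same size, drawn from 20 bins of mean expression. A list outside the central 95% is said to stand apart. The named genes were also chosen by a rule fixed then. It takes the 12 highest and 12 lowest genes with a mean of at least 5 RPKM, up to 4 members per list with the ratio farthest from 0, the individually fixed genes, and the 5 highest and 5 lowest lncRNAs with a mean of at least 1 RPKM. Because the last part gave lncRNAs of few reads, 5 per direction among those with at least 100 reads and the 3 most abundant were added after the data were seen, and so were the genes LOC100134871, Ptprc and Ddx3y. Of the genes the rule takes, 2 are not reported here.

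Gene length was related to the ratio. Over the 8761 genes with at least 200 reads the Spearman coefficient across genes was -0.20, and the median log2 ratio went from 0.055 in the shortest to -0.064 in the longest of 10 classes of length. Random lists matched on length (10 bins of expression by 5 of length) and ratios with a quadratic trend on log2 length removed were added for this reason. For 4 genes the listed length differed between the libraries. Of 13706 gene symbols, 12608 are current and 872 are older names in a RefSeq table of another assembly, GRCr8, from which only names were used, and 226 matched neither. The alternatives tried were other pseudocounts, filters, scalings and thresholds, list means, unmatched random lists and sums over duplicate symbols.

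The steps were tested on simulated data with 200 genes changed 2-fold. For the 13706 protein-coding genes the median recovered log2 ratio was 0.94 for increases and -0.89 for decreases, and the interval held the true ratio in 96.5% of them. For the 18361 lncRNAs these were 0.97, -0.98 and 97%. Of 200 random lists of 20 genes with no shift, 2% fell outside the central range, and all lists (100%) shifted by 0.25 lay above it. The simulated reads held counting error only, with no length trend and no genes that vary together. These rates therefore need not hold for the real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.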

Results

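Spontaneously hypertensive rats, an inbred strain that develops high blood pressure and cardiac hypertrophy, were given the herbal preparation Jiangya Kangxian formula at its high dose (KXH, 9.6 g/kg into the stomach) or distilled water for 12 weeks, and total RNA of the myocardium was sequenced. There was 1 library per group. The labels do not say whether a library came from 1 animal or from a pool. The protein-coding table summed to 14.1 M reads in the KXH library and 15.1 M in the water library (M, 1000000), and the long non-coding RNA (lncRNA) table to 2.93 M and 3.18 M reads. Reads were listed for 13241 protein-coding genes in the KXH library and 13327 in the water library. With 1 library per group, no difference below has a replicate check and no test between the treatments was made. Ratios are therefore given with 95% exact intervals that cover counting error only, and "higher" and "lower" describe these 2 libraries. Animal-to-animal variation is not contained in any interval.

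The comparison of KXH with water asks which myocardial transcripts differ in hypertensive rats that received the formula, with cardiac remodelling and mitochondrial function named as the interest of the study. In the KXH library the cardiac stress hormone transcripts Nppb and Nppa, skeletal alpha-actin Acta1 and connective tissue growth factor Ctgf were higher than in the water library, by 1.93, 1.56, 1.55 and 1.90 times. Osteopontin (Spp1), the fatty acid transporter Cd36, and 24 of 28 measured interferon-induced genes were lower, Spp1 by 7.63 times. Globin and other erythroid transcripts were lower as well, and genes of the respiratory chain lay within 1.3 times of the water level.

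Over the 10467 protein-coding genes with a mean of at least 1 RPKM (reads per kilobase per 1000000 reads), the log2 levels of the libraries correlated across genes with a Pearson coefficient of 0.993 and a Spearman coefficient of 0.992. Genes are not independent replicates, so these values describe how alike the profiles were. The median log2 ratio of KXH over water was -0.02. Among the 4619 genes with at least 1000 reads in sum, the log2 ratios spread with a robust SD of 0.11, against 0.053 from counting error alone. Only 4 genes were at least 2-fold higher and 11 at least 2-fold lower on the log2(RPKM + 1) scale, where counting error alone gave 0.22 and 0.30 genes on average. The counting interval lay above 1 for 1170 genes and below 1 for 1702.

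The highest ratio belonged to LOC257642, at 46.9 RPKM in the KXH library and 4.89 in the water library, which is 9.61-fold higher (95% interval 6.79 to 13.96; 322 and 36 reads). Kcne1, a subunit of the slow delayed rectifier potassium channel, followed at 8.51 and 3.28 RPKM, 2.59-fold higher (1.66 to 4.15). The other 2 genes past 2-fold on the log2(RPKM + 1) scale were Tctex1d2 (37 and 8 reads) and the chemokine Xcl1 (30 and 8 reads). Both rested on few reads and are named here after their values were seen. The secreted phospholipase Pla2g2a was 1.98-fold higher (1.75 to 2.24) and the nuclear receptor Nr4a3 2.07-fold higher (1.83 to 2.34). Wfdc21, Gpr17, Glrx, Rwdd1 and LOC100911177 were also among the 12 highest genes, with ratios from 1.61 for LOC100911177 to 2.09 for Wfdc21, each with an interval above 1.

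At the other end, LOC287167, an alpha-globin gene, had 101 reads in the water library and none in the KXH library. Against a floor of 3 reads in the KXH library it was at least 31.3-fold lower. That floor leaves out the counting error of the water reads, and the exact interval of the ratio ended at 0.040. Spp1, a matrix protein made by macrophages and stressed muscle, stood at 4.11 RPKM in the KXH library and 31.4 in the water library, 7.63-fold lower (6.09 to 9.66). Serhl2 was 3.41-fold lower (2.85 to 4.09), the mitochondrial nuclease Endog 2.78-fold lower (2.14 to 3.64) and the retinol saturase Retsat 2.27-fold lower (2.14 to 2.40), the last at 61.9 against 140.4 RPKM. The transmembrane glycoprotein Gpnmb was 1.97-fold lower (1.75 to 2.22). Cd36 was 1.83-fold lower (1.78 to 1.88) at 229 against 420 RPKM, and Amd1, which makes the decarboxylated precursor for polyamine synthesis, 1.77-fold lower (1.68 to 1.87). The remaining genes among the 12 lowest were RT1-Ba, RT1-CE14, LOC689064 and Fhit, between 1.86-fold and 2.06-fold lower. Reads of globin and RT1 genes can be split among near-identical copies, so their single values are uncertain.

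**Figure D1:**
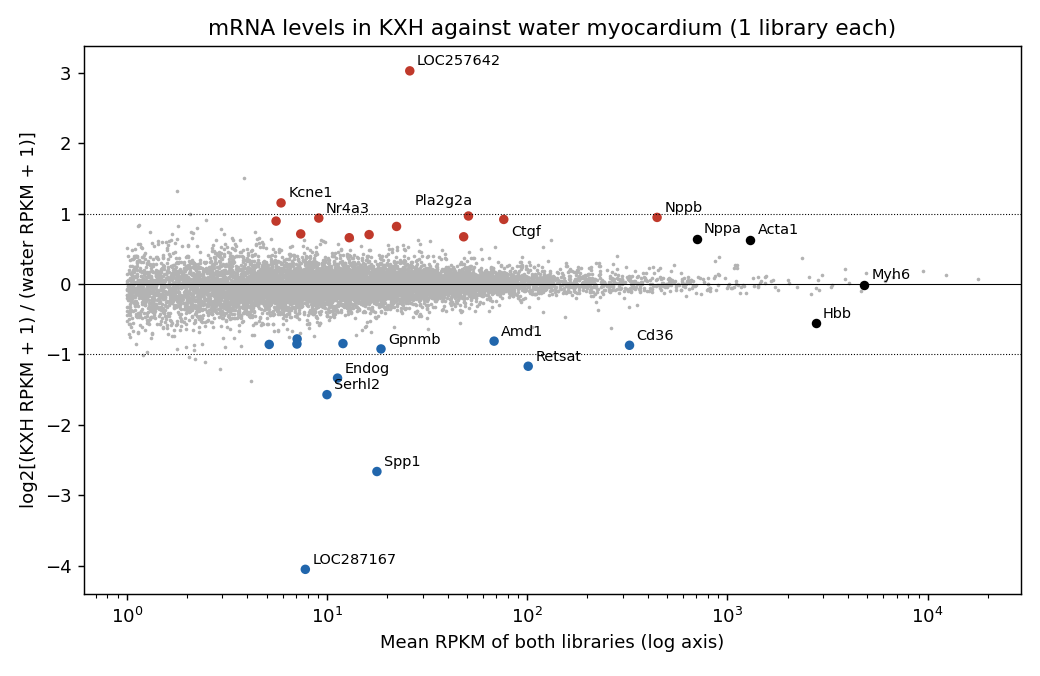
Each point is 1 of 10467 protein-coding genes, with its mean RPKM of both libraries on the horizontal log axis and its log2 ratio of KXH over water, with 1 added to each RPKM, on the vertical axis. Dotted lines mark 2-fold. Red and blue points are the 12 highest and 12 lowest genes with a mean of at least 5 RPKM, and black points mark Nppa, Acta1, Hbb and Myh6, of which Myh6 turns its direction with the scaling. LOC257642 lies highest at 3.03, and LOC287167 and Spp1 lie lowest at -4.05 and -2.66.

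Cardiac remodelling genes were examined as lists fixed beforehand, and each list's median log2 ratio was placed among 10000 random lists of the same size and expression, as a description of these libraries. The hypertrophy and fetal gene program had a median of 0.25, above all random lists (100th percentile), with 13 of its 16 measured members higher in the KXH library and the counting interval of 11 above 1. Of its measured members, 6 are also on another list, among them Ctgf (matrix) and Nppa and Myl4 (atrial). Nppb, which encodes B-type natriuretic peptide, was at 586 against 304 RPKM (1.93-fold, 1.84 to 2.02), and Nppa, which encodes the atrial peptide, at 854 against 547 RPKM (1.56-fold, 1.52 to 1.61). Acta1 was at 1578 against 1022 RPKM (1.55-fold, 1.52 to 1.57), and Ctgf at 100.1 against 52.6 RPKM (1.90-fold, 1.80 to 2.02). Myl4 and Sln, both also on the atrial list, were 1.69-fold (1.16 to 2.49) and 1.61-fold (1.01 to 2.60) higher at low levels. The slow myosin heavy chain Myh7 was 1.16-fold higher (1.15 to 1.16). The fast chain Myh6 was at 4794 and 4824 RPKM, a ratio of 0.994 (0.989 to 0.998) that passes to the other side of 1 when ratios are centred on their median. The calcium pump Atp2a2 had a ratio of 0.942 (0.937 to 0.948). Adult sarcomere genes had a median of 0.047 (90.1st percentile) and calcium handling and ion channel genes one of 0.006 (61.1st percentile), both within the central 95% of random lists.

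The extracellular matrix and fibrosis list also lay above all random lists, with a median of 0.10 and 22 of 35 measured members higher. A bootstrap over its members gave -0.031 to 0.199 for this median, a range that includes 0. Of its measured members, 7 are also on another list. Its members went both ways. Ctgf, thrombospondin 4 (Thbs4, 1.63-fold, 1.40 to 1.90) and the crosslinking enzyme Loxl1 (1.55-fold, 1.32 to 1.82) were higher, whereas Spp1 was the lowest member. The fibrillar collagens Col1a1 and Col3a1 were each 1.07-fold higher (1.03 to 1.12 and 1.05 to 1.10), and periostin (Postn) 1.21-fold (1.02 to 1.44). For Tgfb1 the ratio was 1.07 with an interval of 0.911 to 1.26, so no difference was detectable at this depth. Transforming growth factor beta signalling genes had a median of -0.048 (20.4th percentile). Genes of the renin-angiotensin-aldosterone system and of blood pressure control had one of -0.02 (53.3rd percentile). Within that list Ace was 1.42-fold lower (1.18 to 1.71) and Nos2 2.07-fold lower (1.44 to 3.01), whereas Nos1 was 2.08-fold higher (1.51 to 2.89). Agt and Agtr1a had intervals that include 1.

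**Figure D2:**
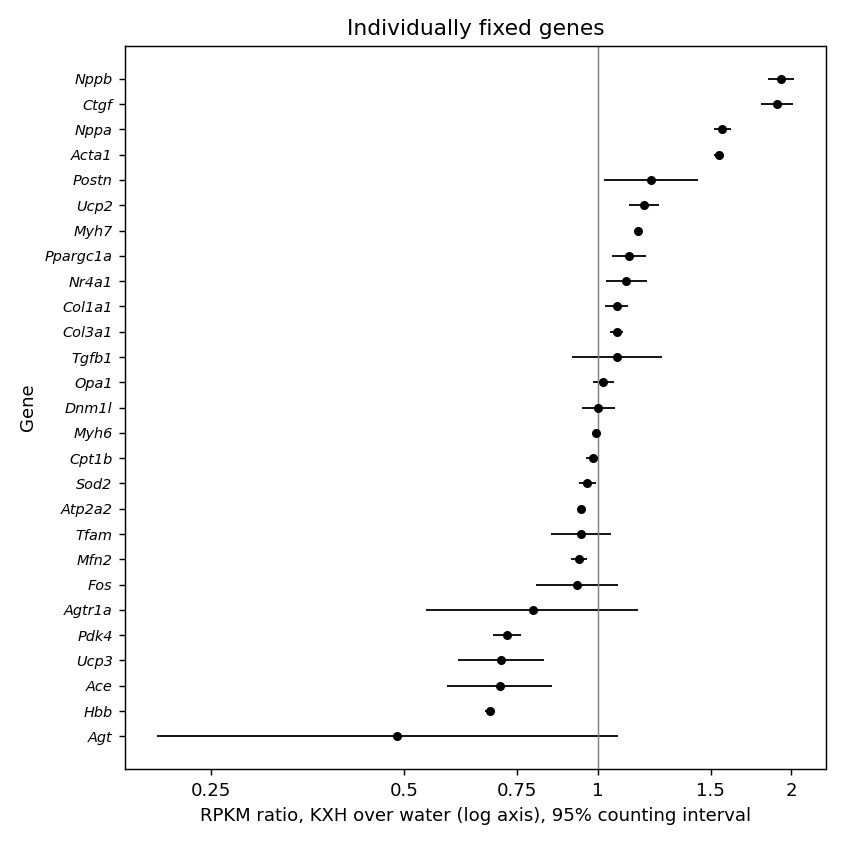
RPKM ratio of KXH over water on a log axis for 27 of the genes fixed individually beforehand, with horizontal bars for the 95% exact counting interval of 1 library against 1 library. Nppb, Ctgf, Nppa and Acta1 lie between 1.55 and 1.93, Hbb lies at 0.680, and the point for Myh6 at 0.994 turns to the other side of 1 under median-centring.

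Most lists of mitochondrial genes had medians close to 0. Subunits of respiratory complex I had a median log2 ratio of 0.036 (88.7th percentile, 24 of 34 higher) and those of complexes II to V a median of 0.045 (95th percentile, 27 of 40 higher), both within the central 95% of random lists. Among them Atp5j was 1.23-fold higher (1.15 to 1.31) and Uqcrb 1.22-fold higher (1.17 to 1.27). Mitochondrial ribosomal proteins stood apart at 0.059 (99.8th percentile, 34 of 49 higher). Among random lists also matched on gene length, an alternative added after the data were seen, they lay at the 89.6th percentile. Tricarboxylic acid cycle genes lay just below the central range at -0.041 (2.13th percentile, 13 of 17 lower). They lay inside it with length matching (2.81st percentile) and by their mean (3.12th). The same held with the length trend removed (10.4th) and among lists not matched on expression (30.6th). Their lowest member, Sucla2, was 1.11-fold lower (1.07 to 1.14). No reads were listed under the names used here for transcripts of the mitochondrial genome.

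Fatty acid uptake and oxidation genes had a median of -0.001 (31st percentile), with 15 members higher and 16 lower, while their mean of -0.055 lay at the 0.79th percentile. The members farthest from 0 were lower. Besides Cd36, these were Pdk4, which restrains glucose oxidation (1.38-fold lower, 1.32 to 1.45), and the uncoupling protein Ucp3 (1.41-fold lower, 1.21 to 1.65). The mitochondrial carnitine transferase Cpt1b had a ratio of 0.982 (0.960 to 1.01). Glycolysis and glucose uptake genes had a median of -0.049 (2.32nd percentile). They lay inside the central range with length matching (3.44th percentile), with trimmed-mean scaling (2.58th), by their mean (10th) and among lists not matched on expression (21.5th). Eno3 was 1.29-fold lower (1.24 to 1.34) and Eno1 1.21-fold higher (1.18 to 1.24). Genes of mitochondrial biogenesis, dynamics and mitophagy had a median of -0.02 (28.0th percentile) and a mean of 0.002. The coactivators Ppargc1a and Ppargc1b were 1.12-fold (1.05 to 1.19) and 1.25-fold (1.16 to 1.35) higher. The fusion and fission genes Opa1 and Dnm1l had intervals that include 1, and Mfn2 was 1.07-fold lower (1.04 to 1.10). Antioxidant defence genes had a median of -0.01 (41.9th percentile) and a mean of 0.003, with Sod2 at a ratio of 0.964 (0.937 to 0.993). Oxidases that produce reactive oxygen species had a median of -0.05 (26.9th percentile). Centring all log2 ratios on their median adds 0.02 and turns the sign of 7 of the 42 list medians, those between -0.02 and 0, none of which stood apart.

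Interferon-induced genes were lower in the KXH library. Their median log2 ratio was -0.31, below all random lists, with 24 of 28 measured members lower and 19 counting intervals below 1. The guanylate-binding protein Gbp5 was 1.71-fold lower (1.41 to 2.08), the immunity-related GTPase Igtp 1.58-fold (1.38 to 1.81), the ubiquitin-like Isg15 1.56-fold (1.11 to 2.19) and the antiviral Rsad2 1.51-fold (1.32 to 1.73). Genes of the rat major histocompatibility complex (RT1) had a median of -0.19, also below all random lists, with 14 of 18 lower. The class II genes RT1-Bb and RT1-Ba were 3.44-fold (2.41 to 5.02) and 2.06-fold (1.47 to 2.90) lower. The class I gene RT1-A2 was 1.65-fold lower (1.42 to 1.92), whereas its close relative RT1-A1 was 1.54-fold higher (1.46 to 1.62), and reads of such near-identical genes can be split between them. Among genes with a mean of at least 5 RPKM the RT1 median was -0.08, within the central range. Inflammatory cytokines and targets of NF-kB had a median of -0.07 (23.8th percentile), while their mean of -0.15 lay below the central range (2.13th percentile).

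Markers of other cell types differed between the libraries beside these groups. Endothelial markers had a median of -0.16 and smooth muscle and pericyte markers one of -0.22, both below all random lists, with 15 of 16 and 11 of 12 members lower. Flt1 was 1.23-fold lower (1.18 to 1.27), and smooth muscle myosin Myh11 1.53-fold lower (1.39 to 1.69). Fibroblast markers lay higher at 0.10 (99.4th percentile, 12 of 14 higher), with Pi16 1.46-fold (1.31 to 1.63) and Tcf21 1.41-fold (1.15 to 1.72) above the water level, and 6 of the 14 are also on another list. Mesothelial and epicardial markers had a median of 0.30 over 8 genes of low expression (99.99th percentile), of which 6 were higher and 5 had intervals that include 1. A bootstrap over these members gave -0.14 to 0.45 for the median, a range that includes 0. Macrophage and monocyte markers had a median of -0.017 (55.8th percentile), although Cd68 was 1.74-fold lower (1.34 to 2.27). Markers of T, B and natural killer cells had a median of -0.11 (34.3rd percentile) over 7 genes. Ventricular markers had a median of 0.10 (97.7th percentile), with 5 of 9 measured members higher and a bootstrap range over members of -0.25 to 0.27. They lay inside the central range with length matching (96.9th percentile), a pseudocount of 0.1 (97.3rd), the length trend removed (94.1st) and by their mean (87.6th). Atrial markers had a median of -0.03 (36.4th percentile). The atrial mean was 0.04.

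Erythroid and globin transcripts had the lowest median of the 42 lists, -0.60, with all 8 measured members lower and 5 counting intervals below 1. Placing LOC287167 at its bound instead of its fitted value leaves this median as it is, because the gene ranks lowest in either case. The most abundant member, the beta-globin Hbb, was at 2234 against 3283 RPKM, 1.47-fold lower (1.44 to 1.5). The erythroid haem synthesis enzyme Alas2 was 1.58-fold lower (1.43 to 1.74) and the red cell anion exchanger Slc4a1 1.81-fold lower (1.49 to 2.19). The chaperone Ahsp had 24 and 26 reads and an interval of 0.545 to 1.80.

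Immediate early, heat shock and endoplasmic reticulum stress genes had higher medians in the KXH library, and atrophy and apoptosis genes lower ones. Immediate early genes had a median of 0.12 (100th percentile, 22 of 32 higher), with Nr4a3 at 2.07-fold, Egr2 at 1.97-fold (1.34 to 2.93) and Arc at 1.78-fold (1.29 to 2.49). Fos, a widely used activity marker, had a ratio of 0.929 with an interval of 0.801 to 1.08. Heat shock proteins and chaperones had a median of 0.11 (99.99th percentile, 20 of 24 higher), with Hsp90aa1 at 1.28-fold (1.12 to 1.46) and Hspb7 at 1.20-fold (1.18 to 1.22). Endoplasmic reticulum stress genes had one of 0.10 (99.7th percentile, 17 of 19 higher), including the luminal chaperone Hspa5 at 1.20-fold (1.16 to 1.24). Ubiquitin ligases and atrophy genes had a median of -0.10 (0.31st percentile; 7.0th among lists not matched on expression), with 6 of 11 members lower and 5 higher, led by atrogin-1 (Fbxo32) at 1.32-fold lower (1.24 to 1.41). Apoptosis genes had a median of -0.12 (0.61st percentile). They lay inside the central range by their mean (-0.10, 4.41st percentile) and with the length trend removed (-0.07, 2.88th percentile). Both the pro-apoptotic Bax and the anti-apoptotic Bcl2 were lower, by 1.43 times (1.14 to 1.79) and 1.42 times (1.15 to 1.76). In all, 20 of the 42 lists with at least 5 measured members stood apart from the random lists, 10 above and 10 below. With random lists matched on length as well, 16 did, and 15 did in both. If genes varied independently, 2.1 lists would stand apart. Members of a list can vary together and some lists share members, so 2.1 is not what unrelated hearts would give.

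**Figure D3:**
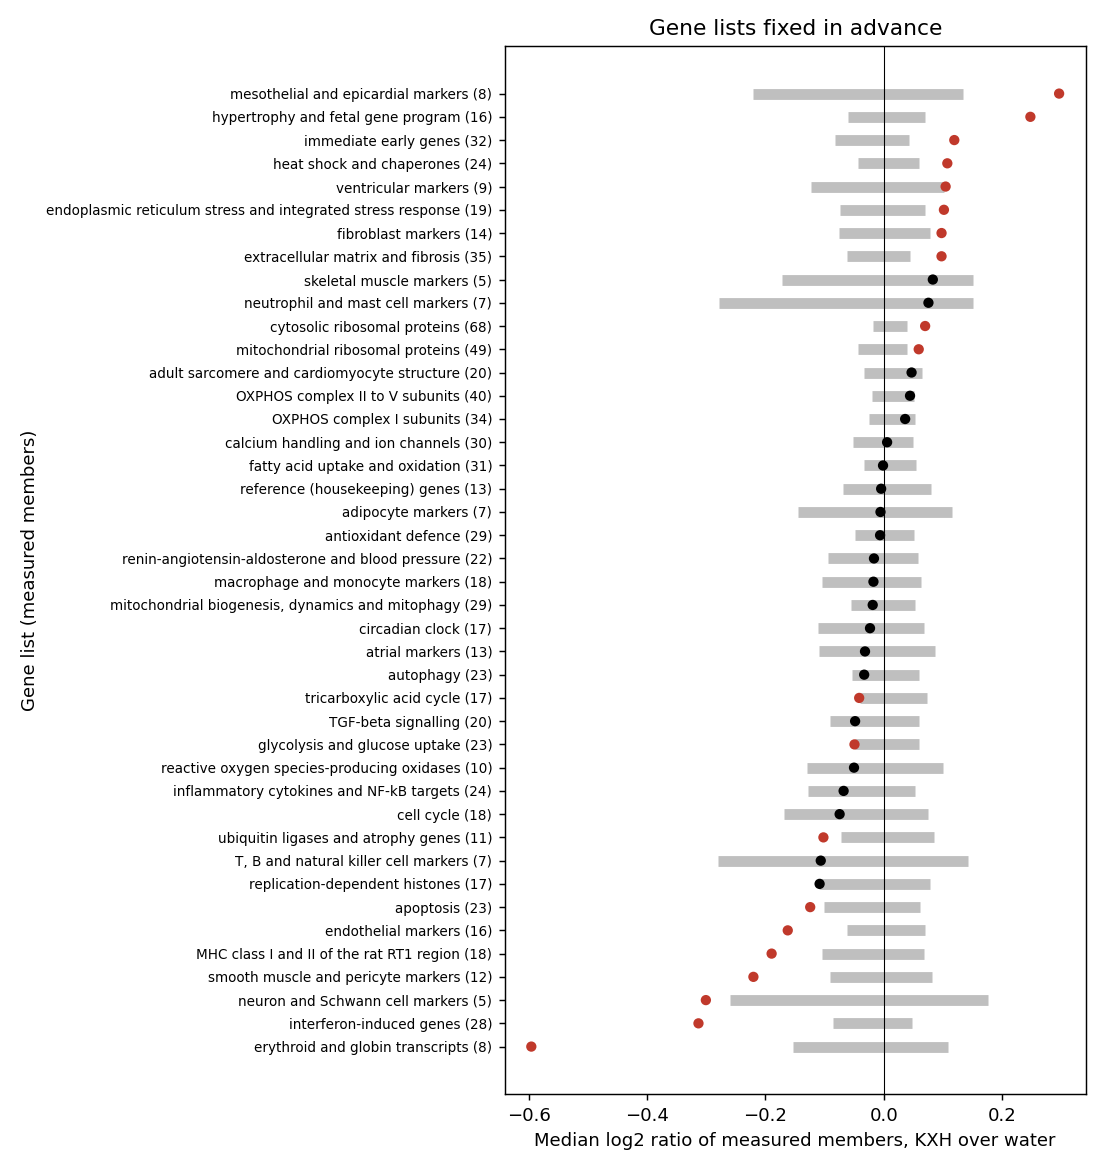
Median log2 ratio of KXH over water for the 42 gene lists with at least 5 measured members, given in brackets, on the horizontal axis. Grey bars span the central 95% of 10000 random lists of the same size and expression, and red points lie outside them, as 20 of the lists do, from erythroid and globin transcripts at -0.60 to mesothelial and epicardial markers at 0.30. The sign of 7 medians between -0.02 and 0, all black points, turns under median-centring.

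For lncRNAs the same comparison was made over 17071 transcripts with a mean of at least 0.5 RPKM. The farthest apart among well-covered transcripts was 1 lncRNA. NONRATT031966.1, on chromosome 14 from 46643222 to 46645093 in the coordinates of the table, had 36444 reads in the KXH library and 3424 in the water library, 11.5-fold higher (11.1 to 12.0), and was the only lncRNA with at least 1000 reads that was at least 2-fold apart. Its sequence was not analysed here, so it is not known whether its reads come from ribosomal RNA, which total RNA holds in abundance. The 3 most abundant lncRNAs by mean RPKM lay between 1.03 and 1.18 times the water level. NONRATT028802.2 had a ratio of 1.05 (1.04 to 1.06), NONRATT010872.2 one of 1.03 (1.02 to 1.04) and NONRATT008258.2 one of 1.18 (1.16 to 1.19). These and the lncRNAs of at least 100 reads were chosen after their values were seen.

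In all, 1396 lncRNAs were at least 2-fold higher and 1865 at least 2-fold lower on the log2(RPKM + 0.1) scale, but counting error alone gave 1115 and 1058 on average. Most had few reads. Below 20 reads in sum, 1191 were higher and 1508 lower, against 1051 and 1033 from counting error. From 100 reads to below 1000, 8 were higher and 15 lower, against 0.24 and 0.32. Log2 levels of the 2 libraries correlated across lncRNAs with a Pearson coefficient of 0.876 and a Spearman coefficient of 0.95. The 10 transcripts named by the rule set beforehand all had 6 to 16 reads in one library and none in the other. The best covered of them was NONRATT014141.2 on chromosome 19 from 25812981 to 25813457, with 16 reads in the KXH library and none in the water library, at least 5.78-fold higher against the floor of 3 reads. Among those with at least 100 reads, NONRATT028522.2 (chromosome 8, 53026101 to 53026759) was 4.14-fold higher (2.56 to 6.96). NONRATT033384.1 (chromosome 6, 44006624 to 44009412) was 4.57-fold lower (2.90 to 7.5), and NONRATT017141.2 (chromosome 20, 5377892 to 5418013) 3.14-fold lower (2.67 to 3.70). The tables pair no gene names with these transcripts, and whether each lies in or beside a coding gene was not analysed here.

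**Figure D4:**
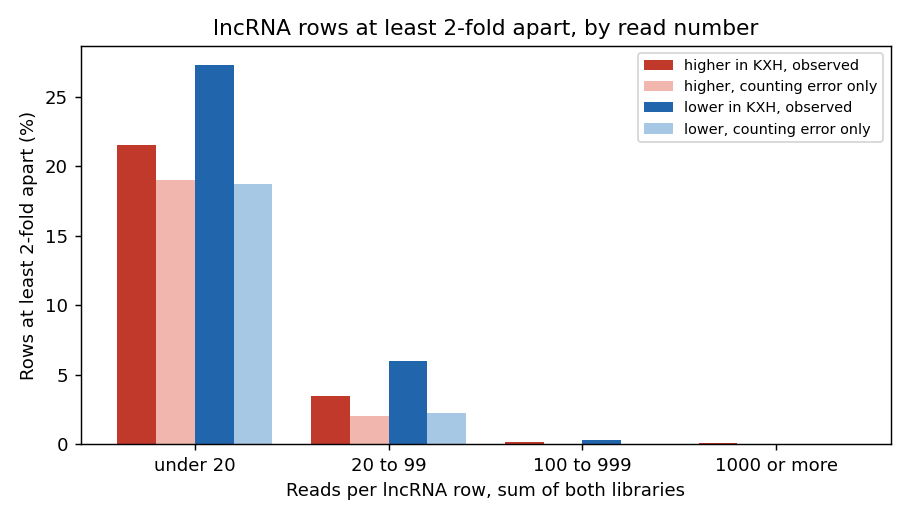
Share of lncRNAs at least 2-fold higher (red) or lower (blue) in the KXH library, in percent of the transcripts of each read class on the horizontal axis, with the mean share from 50 simulations of counting error alone in pale bars. Most 2-fold differences lie below 20 reads, where 1191 lncRNAs were higher and 1508 lower.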

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

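With 1 library per group no library could be left out, and no paired analysis was possible because each group has a single library. Alternatives on gene length and on rows of at least 200 reads were added after the data were seen. Counts of genes past a threshold moved most. The 4 mRNAs at least 2-fold higher became 19 with a pseudocount of 0.1, 2 with a mean of at least 5 RPKM, 52 at 1.5-fold and 1 with at least 200 reads, and the 11 lower became 41, 5, 81 and 4. The 1396 lncRNAs higher became 696 with a mean of at least 2 RPKM, 2403 at 1.5-fold and 2 with at least 200 reads, and the 1865 lower became 996, 3318 and 6. These follow from the threshold, or from how many genes are kept, and from the smaller pseudocount, which shrinks low values less. The other 14 alternative counts, including both other scalings and no filter, stayed within 1.5 times of the main ones.

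Of 330 alternative list results, 301 kept their place inside or outside the central range, 21 moved into it and 8 moved out, 5 of these for the histones. Among mitochondrial lists, complexes II to V (0.045) moved above the range with random lists not matched on expression (98.7th percentile). The tricarboxylic acid cycle moved inside with its mean (-0.040), with unmatched lists (-0.041), with lists matched on length (-0.041) and with the length trend removed (-0.012). The mean of fatty acid oxidation genes (-0.055) lay below the range. Mitochondrial ribosomal proteins moved inside with length matching (0.059) and with the trend removed (0.033). The cause was not tested beyond what the length alternatives show. The hypertrophy, matrix, interferon and erythroid lists kept their place under each alternative run for them. Of 657 alternative ratios of named genes with reads in both libraries, 638 stayed within their counting interval or moved by less than its half-width, 17 moved farther, and that of Myh6 reversed, to 0.010 when median-centred and 0.010 with trimmed-mean scaling, both of which add 0.02 to each log2 ratio. Every symbol stood once, so summing duplicates had nothing to act on. The planned comparison of lncRNAs with neighbouring mRNAs was not run, since the tables give no mRNA positions. Below 20 reads, where 1191 lncRNAs were higher and 1508 lower, counting error alone gave 1051 and 1033, so most 2-fold differences there lie within what this depth can produce.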

Other observations

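All tests of explanations below were chosen after the results were seen. Among gene groups not described above, cytosolic ribosomal protein genes were higher, with a median log2 ratio of 0.07 (100th percentile, 49 of 68 higher), but lay at the 96.2nd percentile among length-matched lists. Rplp2 was 1.5-fold higher (1.21 to 1.86). Replication-dependent histones had a median of -0.11 (2.71st percentile), just inside the central range, and lay below it under 5 alternatives, namely with a mean of at least 5 RPKM (-0.15, 0.12th percentile), median-centred (2.43rd), by their mean (-0.20, 0.24th), with length matching (1.97th) and with the length trend removed (0.10th). The linker histone Hist1h1d was 1.62-fold lower (1.27 to 2.07). Markers of neurons and Schwann cells had a median of -0.30 (1.02nd percentile) over 5 genes, of which Sox10 was 2.32-fold lower (1.61 to 3.38) and Prph 1.51-fold higher (1.14 to 2.0), and their mean of -0.15 lay within the central range. Autophagy genes (-0.03, 12.2nd percentile), clock genes (-0.02, 49.0th percentile, mean 0.015), cell cycle genes (-0.07, 30.7th percentile), reference genes (-0.004, 41.6th percentile), adipocyte markers (-0.01, 56.7th percentile, mean 0.02), skeletal muscle markers (0.08, 89.6th percentile) and neutrophil and mast cell markers (0.08, 90.3rd percentile, mean -0.10) lay within it too. Platelet markers (4 measured) and proteins abundant in liver, pancreas or lung (1 measured) were too few for a median. Of the Y-linked genes, Eif2s3y was at 30.8 RPKM in the KXH library and 27.1 in the water library, and Ddx3y had 24 and 12 reads.

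Neighbouring lncRNAs had related ratios. Pairs were lncRNAs with at least 100 reads that followed each other directly in genome order. Over 1090 pairs that lay up to 10 kb apart without overlap, the log2 ratios correlated with a Pearson coefficient of 0.23 and a Spearman coefficient of 0.22. For the Pearson coefficient, 10000 shuffles gave -0.06 to 0.06. The two-sided permutation p was 0.0001, the smallest these shuffles can give (0.0002 after Benjamini-Hochberg adjustment over both kinds of pair). Over 351 overlapping pairs the Pearson coefficient was 0.063 (p = 0.2412, adjusted 0.2412). Pairs are not independent replicates, and adjoining pairs can share a lncRNA. The shuffles ignore this, so the p-values can be too small. LOC257642 and NONRATT031966.1 were both about an order of magnitude higher in the KXH library, at 9.61-fold and 11.5-fold, and whether they share an RNA, or are carried-over ribosomal RNA, was not tested, since their sequences were not analysed here.

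The natriuretic peptides and other hypertrophy genes were higher in the KXH library. For atrial tissue in the KXH sample the values do not decide, and it stays open. Atrial tissue would raise other atrial transcripts by the Nppa ratio only if atria gave equal shares of each in the water sample. Those shares were not measured, so a held ratio is no support. Of Myl7, Myl4 and Sln, abundant in atria and low here, 2 (Myl4 at 1.69-fold, 1.16 to 2.49, and Sln at 1.61-fold, 1.01 to 2.60) held the Nppa ratio of 1.56 in wide intervals, whereas Myl7, with 13 and 21 reads, had an interval of 0.306 to 1.39. Against atrial tissue, the median of the atrial list was -0.03 (36.4th percentile), and Myl7, Myl4 and Sln together gained 6.24 RPKM where Nppa gained 308. The comparison of gains was first taken to exclude atrial tissue. It was then replaced by the ratios because it assumes an atrial profile not measured here. Removing the length trend left the list's median at 0.26, so length does not account for it, while variation between animals and an effect of the formula stay open and untested.

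Erythroid transcripts were lower in the KXH library. Less blood in that sample is a candidate explanation. All 6 measured members other than Hbb and LOC287167 were lower and 5 of these held the Hbb ratio of 0.680 in their interval. That of Slc4a1 ended just below it, at 0.671. The intervals of 3 of the 5 were wide enough to include 1 as well, so those members cannot tell less blood from no difference. Among these 3, Ahsp had a log2 ratio of -0.009, whose sign turns under median-centring. The allowance of 1 exception was set after the values were seen. LOC287167 is not accounted for in this way, since its ratio at the floor of 3 reads, 0.0319, lies far below the Hbb ratio, and the length trend is not either, as the list's median was -0.60 without it.

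Interferon-induced genes were lower in the KXH library. The median of macrophage and monocyte markers was -0.017 against -0.31, a difference of 0.30 (bootstrap interval over members of both lists 0.12 to 0.42). This argues against a general loss of macrophages as the whole account. List members are not replicates, and a median of general markers cannot exclude fewer macrophages of some kinds, which stays open. Fewer endothelial cells may account for part of the lower interferon-induced genes. Their markers' median of -0.16 differed from that of the interferon genes by 0.15, with an interval of 0.0075 to 0.26 that barely excludes 0, so the evidence against them as the whole is weak, and without the length trend the list's median was -0.28. Other leukocytes stay open. The pan-leukocyte gene Ptprc, chosen after its value was seen, was 1.28-fold lower (1.12 to 1.47) and Nkg7, the lowest marker of T, B and natural killer cells, 2.72-fold lower (1.42 to 5.57), but that list lay within the central range (-0.11, 34.3rd percentile), 5 of its 7 intervals included 1 and Cd28 was 1.37-fold higher (0.979 to 1.93). Infection status, variation between animals and an effect of the formula were not tested.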
